A study of Rattus norvegicus with 12 samples.

How the data were processed

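Whole blood RNA was sequenced from adult male rats of 2 inbred strains, F344 and WKY, with and without chronic restraint stress (CRS). The 12 libraries fell into 4 groups of 3: F344 without stress (NS), F344 after CRS, WKY without stress and WKY after CRS. Groups were taken from the sample labels, which name strain and treatment for each library. The labels do not say outright that each library came from a separate rat, so p-values measure the spread between these libraries. Per the labels' protocols, blood was collected into PAXgene tubes immediately after decapitation and libraries were made with standard Ion Proton protocols.

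The deposited files gave whole-number read counts for 17337 genes per library, not normalised. The submitters' processing notes name cutadapt 1.14, TopHat2 2.1.0, Cufflinks 2.2.1 and genome build rn6, with no role stated for each. The program that made the counts, its annotation and its strand setting are not given in the sources used here. Each file also held 5 rows that name no gene, and these stayed out of library sizes and tests. They took 80.9% to 86.6% of all counts in a library. Reads recorded as ambiguous between features alone took 78.3% to 83.6%, and reads outside any feature 2.31% to 3.89%. Such a share of ambiguous reads lowers the counts of any gene that shares sequence or position with another, so levels of overlapping or duplicated genes are uncertain.

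Genes received 1691956 to 3846263 counts per library. The 3 most abundant features (LOC310926, Rn5-8s and LOC257642) took 88.9% to 94.6% of these, which left 90796 to 419789 counts per library for all other genes. Between 465 and 2982 genes had at least 10 counts in a library. A single count was worth 0.202 to 1.14 CPM (counts scaled to a common library total), so low levels were measured coarsely and intervals cover counting error only.

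Counts were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test (glmQLFit, glmQLFTest) with TMM scaling. The filter filterByExpr with its minimum count of 10 kept 2781 genes. All 12 libraries entered 1 fit of 4 group means without covariates, and p-values were adjusted over the 2781 genes by the Benjamini-Hochberg method, with a threshold of 0.05. CPM are TMM-scaled and given as mean ± SD. Standard errors (SE) of log2 fold changes were derived from the fold change and the F statistic. There were 6 planned contrasts: CRS against NS in each strain, their mean, WKY against F344 under each treatment, and the difference between strains in the CRS response. The mean of both strain contrasts was added after the data were seen.

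Before the data were examined, 25 gene lists were fixed: markers of blood cell types, globin, stress and immune pathways, housekeeping complexes, and tissue carried over at decapitation. Of these, 18 had at least 5 tested genes and were tested with camera (limma 3.58.1, preset correlation of 0.01), adjusted over the 18 lists of a contrast. Camera with an estimated correlation and fry were run beside it. Member genes move together across libraries, which the preset value largely ignores. The CPM of a list's members were also summed per library and compared by two-sided exact permutation within strata, a choice made after the data were seen. With 400 arrangements the smallest possible p is 0.005, and 3 libraries against 3 cannot go below 0.1.

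Named genes followed a rule set before the data were examined. Among genes past the threshold with a mean of at least 5 CPM and an informative symbol, it took the 10 largest fold changes per direction whose groups did not overlap and the 5 smallest p-values per direction. Where no gene passed in a direction, it took the 3 with the smallest p. It also took up to 2 members per direction of each list described. Fkbp5, Tsc22d3, Nr3c1, Per1, Zbtb16 and Il1b were always given. Gene names were looked up in a RefSeq table of assembly GRCr8, which holds 14821 of the 17337 symbols. This is another build than rn6, so it served only for names and neighbours and no coordinates are given.

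The edgeR step was tested on simulated counts for the 2781 genes, with 200 genes changed in each of 5 simulations. For CRS in F344 it recovered 18.2% of 2-fold and 73.2% of 4-fold changes, and for CRS in WKY 19.2% and 82.6%. For CRS averaged over strains it recovered 48.2% and 98.6%. For the strain contrast without stress it recovered 12% and 69.4%, after CRS 21% and 85.2%, and averaged 51% and 98.8%. For the difference in response it recovered 5.2% and 37.6%. False calls made up 4.04% to 6.51% of calls. A shifted list was called by camera in 20 of 20 simulations, and 0 of 340 unshifted lists were called. Genes were drawn independently in these simulations. They therefore could not show false list calls that come from member genes moving together.

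The alternatives tried were DESeq2 size factors, a DESeq2 1.42.0 Wald test, limma-voom with sample quality weights, no or a stricter low count filter, removal of globin genes, fits of the compared groups alone, a replicate block, a threshold of 0.1, and leaving out each library in turn. Removing the 3 most abundant features, and leaving out both shallowest unstressed F344 libraries, were added after the data were seen. Figures were drawn with matplotlib 3.10.9.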

Results

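Blood transcripts were compared between F344 and WKY rats, 2 inbred strains, with and without CRS. Rats aged 70 to 90 days went through contextual fear conditioning, spent 4 weeks in the home cage, and were then restrained for 2 hours daily over 2 weeks or left undisturbed. All were conditioned again and killed 24 hours later. Each of the 4 groups held 3 libraries. Counts outside the 3 most abundant features averaged 168953 ± 68825 (SD, n = 3) in unstressed F344, 348976 ± 69001 in stressed F344, 246647 ± 91283 in unstressed WKY and 281591 ± 44301 in stressed WKY. Unstressed F344 replicate 3 was the shallowest library, with 90796 such counts. In a principal component analysis, unstressed F344 replicates 2 and 3 stood apart from the other libraries, at 21.1 and 40.5 on the first component (25.0% of the variance). Depth therefore differed most within the F344 comparison, although the exact permutation test for 3 against 3 gave p = 0.1, the smallest it allows. Stressed WKY replicate 2 stood apart on the third component (12.0% of the variance), at 28.8 against -12.3 to 10.4 for the other libraries.

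**Figure D1:**
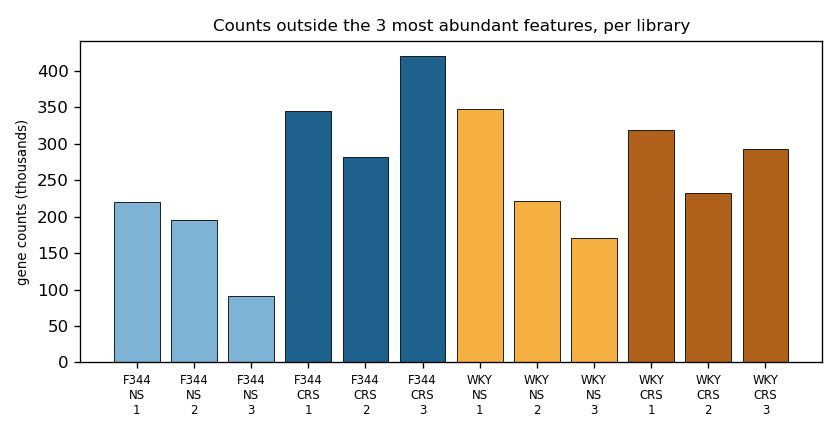
Gene counts outside the 3 most abundant features (vertical axis) for each of the 12 libraries, coloured by group. Values run from 90796 in unstressed F344 replicate 3 to 419789 in stressed F344 replicate 3.

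Globin transcripts, the main product of red cell precursors, were compared as a share of raw counts. Globin made up 2.73% ± 0.709 (SD, n = 3) of gene counts in unstressed F344 and 4.75% ± 0.396 in stressed F344, against 3.34% ± 1.15 and 4.16% ± 0.619 in WKY. The mean difference within strains was 1.42 percentage points (two-sided exact permutation p = 0.02), which did not pass adjusted over 4 comparisons (0.08). Unadjusted, it missed 0.05 without unstressed WKY replicate 3 (1.16 points, exact p = 0.06) or stressed WKY replicate 1 (1.24 points, exact p = 0.055). Of the counts outside the 3 most abundant features, globin took 8.25 points more after CRS (exact p = 0.005, adjusted 0.02), a denominator chosen after the data were seen. With TMM scaling the summed globin genes stood at 35359 ± 10181 and 39619 ± 9691 CPM in unstressed and stressed F344 and at 29641 ± 4450 and 44281 ± 2243 CPM in WKY. Their mean difference of log2 0.38 did not pass (exact p = 0.09, 0.536 adjusted over 25 lists), so any difference depends on the scaling and the denominator. Globin genes are near-identical copies, so single members are uncertain, and reads ambiguous between copies would be missing from their sum and share too. The share of ambiguous reads differed after CRS by -1.12 percentage points within strains (exact p = 0.23). It differed by -0.22 points in F344 and -2.02 in WKY (exact p = 0.3 in WKY). Whether this moved the globin counts was not tested.

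The first question was how restraint changed blood transcripts within F344. Platelet genes were higher after CRS as a list: all 11 tested members had positive fold changes, with a median log2 fold change of 0.56 (camera, adjusted p = 0.00056; adjusted p = 0.76 with an estimated correlation). Examples were Clec1b, a platelet activating receptor (log2 1.17), and Gp1ba, part of the von Willebrand factor receptor (log2 1.26), neither past the threshold alone. The sums in unstressed F344 replicates 1, 2 and 3 were 97.9, 65.2 and 58.3 CPM, against 110 to 127 CPM after CRS, so the difference rested largely on replicates 2 and 3. Without both, the call was lost (camera, adjusted p = 0.328), but replicate 1 is then the lone library of its group and is assumed to vary like the other groups. Adjusted over the list alone, 0 members passed. No single gene passed: edgeR called 0 of 2781, with 130 at an unadjusted p under 0.05 where 139.05 lie by chance, and DESeq2 called 0. Among genes averaging at least 5 CPM and with an informative symbol, those with the smallest p in each direction were Ppp4r2, a phosphatase subunit, at 14.0 ± 2.84 CPM without stress and 4.72 ± 1.25 after CRS (log2 -1.5, SE 0.381, edgeR adjusted p = 0.249), and Npy, the neuropeptide Y gene, at 31.2 ± 18.8 and 76.4 ± 12.9 CPM (log2 1.21, SE 0.350, edgeR adjusted p = 0.530). Foxn4 (log2 -1.99), Bsg (log2 -1.45), Sav1 (log2 2.06) and Zmynd8 (log2 1.08) did not pass either. Among glucocorticoid markers, Fkbp5 (log2 0.09), Tsc22d3 (log2 -0.30) and Per1 (log2 0.65), the receptor Nr3c1 (log2 -0.44) and the cytokine Il1b (log2 0.04) did not pass; Zbtb16 lay below the count filter in all comparisons. Leaving out unstressed F344 replicate 1 gave 5 called genes, Npy among them (edgeR adjusted p = 0.0230).

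In WKY, 3 lists moved with restraint under the preset correlation. Platelet genes were higher, with 11 of 11 members positive and a median log2 fold change of 0.48 (camera, adjusted p = 0.000237; adjusted p = 0.337 with an estimated correlation). Glucocorticoid-responsive genes were higher, with 10 of 13 positive and a median of 0.45 (adjusted p = 0.0341; adjusted p = 0.323 with an estimated correlation), among them the chemokine receptor Cxcr4 (log2 1.05) and glutamine synthetase Glul (log2 0.46), against Fkbp5 (log2 -0.49) and Irs2 (log2 -0.34). MHC class II genes, which present antigen to helper T cells, were lower, with 6 of 6 negative and a median of -0.92 (adjusted p = 0.000777; adjusted p = 0.323 with an estimated correlation), including RT1-Ba (log2 -1.13) and RT1-Db1 (log2 -1.53). In each list 0 members passed adjusted over the list alone. The platelet sums were 151, 146 and 77.4 CPM in unstressed WKY replicates 1, 2 and 3, against 133, 223 and 200 CPM after CRS. Without unstressed WKY replicate 3 the rise of the sum fell from log2 0.60 to 0.29 and the call was lost (adjusted p = 0.295). The glucocorticoid call held in 3 of the 12 leave-outs, with its highest adjusted p without stressed WKY replicate 3 (0.206). Without both shallowest unstressed F344 libraries it was 0.0848. For single genes edgeR called 0 of 2781, with 161 at an unadjusted p under 0.05, and DESeq2 called 0; leaving out unstressed WKY replicate 1 gave 2, Foxe1 (edgeR adjusted p = 4.38e-05) and Sav1 (0.000285). With the same limits on level and symbol, the 3 smallest p-values in each direction belonged to Foxe1 (log2 -2.33, SE 0.510, edgeR adjusted p = 0.15), Sav1 (log2 -2.14), Rem2 (log2 -1.48), the iron-sulfur cluster scaffold Iscu (log2 1.5), the iron exporter Slc40a1 (log2 1.28) and Stat5b (log2 1.18). Tsc22d3 (log2 0.45), Nr3c1 (log2 -0.39), Per1 (log2 0.51) and Il1b (log2 0.35) did not pass.

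Averaged over strains, 1 gene was lower after CRS, Ppp4r2 (log2 -1.34, SE 0.265, edgeR adjusted p = 0.0356), which went from 12.8 ± 6.60 to 5.46 ± 0.729 CPM in WKY. Of 100 groupings of the libraries, the real one among them, 25 gave at least 1 called gene, so chance could not be excluded. Npy came next, at 31.5 ± 10.8 and 66.3 ± 25.8 CPM in WKY (log2 1.13, SE 0.245, edgeR adjusted p = 0.0646), and did not pass. It passed by DESeq2 (adjusted p = 0.0181), limma-voom (0.00602), with no filter (9.09e-05) and with the replicate block (0.0131), which called 2 genes in this contrast. It also passed without unstressed F344 replicate 1 (0.00155), unstressed WKY replicate 2 (0.0355), stressed WKY replicate 1 (0.0176) or stressed WKY replicate 3 (0.0374), and had its highest adjusted p over the alternatives, 0.909, without both shallowest unstressed F344 libraries. DESeq2 called 3 genes, and 197 had an unadjusted p under 0.05 in edgeR. Platelet genes were higher, with 11 of 11 members positive, a median log2 fold change of 0.46 and 3 members past 0.05 adjusted over the list alone (camera, adjusted p = 3.64e-07; adjusted p = 0.493 with an estimated correlation). They included Clec1b (log2 0.96) and Vwf, the von Willebrand factor gene (log2 0.68). Ribosomal protein genes were higher with a median of 0.19, 53 of 72 positive (camera, adjusted p = 0.0410; adjusted p = 0.512 with an estimated correlation), an example being Rpl29 (log2 0.65). The Ppp4r2 call was lost in 7 of 12 leave-outs and without both shallowest unstressed F344 libraries (edgeR adjusted p = 0.587), with log2 fold changes from -1.47 to -1.09 over all alternatives. The count of called genes was 0 without unstressed F344 replicate 2 or 3, unstressed WKY replicate 3, stressed F344 replicate 1 or stressed WKY replicate 2. It was 5 without unstressed F344 replicate 1, and 4 without unstressed WKY replicate 2 or stressed WKY replicate 3. The ribosomal call held in 7 of 12 leave-outs and was lost without unstressed F344 replicate 1, unstressed WKY replicate 3, stressed F344 replicate 3, or stressed WKY replicate 1 or 2 (adjusted p from 0.0652 to 0.329). Iscu (log2 0.90), Fkbp5 (log2 -0.20), Tsc22d3 (log2 0.07), Nr3c1 (log2 -0.41), Per1 (log2 0.58) and Il1b (log2 0.19) did not pass. The fold changes of both strains correlated across genes with Pearson's r = 0.0878 and Spearman's rho = 0.0852 (permutation p = 0.198 from 100 draws), where genes are not independent replicates.

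**Figure D2:**
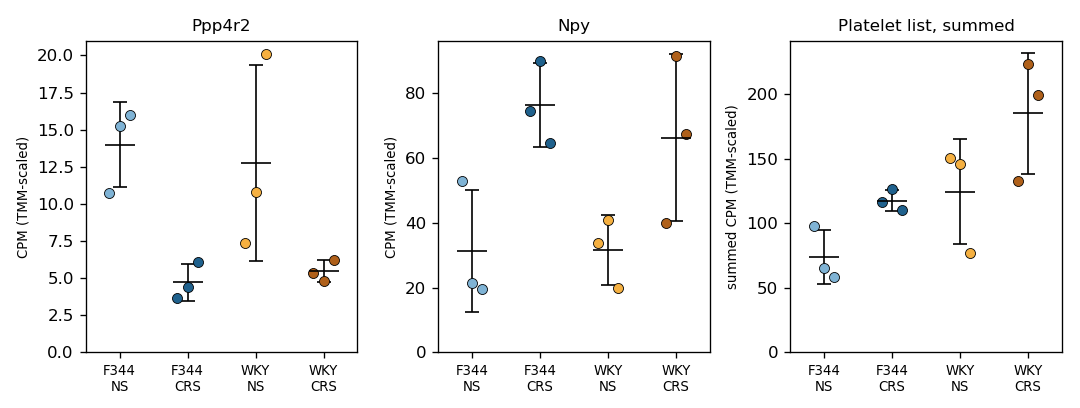
Levels of Ppp4r2 and Npy (CPM) and the summed CPM of the platelet list in the 4 groups, with 1 point per library, horizontal bars for means and error bars for SD (n = 3). Ppp4r2 averaged 14.0 and 12.8 CPM without stress and 4.72 and 5.46 CPM after CRS in F344 and WKY.

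Strain was compared first in unstressed rats. Interferon-stimulated genes were higher in WKY: 24 of 28 tested members were positive, the median log2 difference was 0.68, and 4 passed over all genes and 12 adjusted over the list alone (camera, adjusted p = 2.97e-09; adjusted p = 0.0312 with an estimated correlation). Irf7, a master regulator of type I interferon responses, stood at 254 ± 30.9 CPM in WKY and 55.3 ± 4.72 in F344 (log2 2.19, SE 0.297, edgeR adjusted p = 8.96e-06), and Oas1a, an antiviral enzyme, was also higher (log2 3.74). MHC class I genes were higher, with 12 of 16 positive and a median of 0.86 (camera, adjusted p = 0.00105; adjusted p = 0.144 with an estimated correlation); 2 passed over all genes and 7 adjusted over the list alone, including RT1-S3 (log2 1.72) and RT1-CE5 (log2 1.83). RT1 genes are close copies that differ between strains, so reads can shift between them. T cell genes were lower, 12 of 15 negative with a median of -0.56 (camera, adjusted p = 0.00588; adjusted p = 0.124 with an estimated correlation), with 2 past 0.05 adjusted over the list alone; Cd247 (log2 -1.27) and Ubash3a (log2 -1.71) led. Platelet genes were higher, 10 of 11 positive with a median of 0.70 (camera, adjusted p = 0.00662; adjusted p = 0.517 with an estimated correlation), led by Thbs1 (log2 1.08) and Vwf (log2 1.01), with 0 past 0.05 adjusted over the list alone. The T cell call was lost without unstressed F344 replicate 1 (camera, adjusted p = 0.0855). The platelet call was lost without unstressed F344 replicate 2 or 3, or unstressed WKY replicate 1 or 2 (adjusted p = 0.0630, 0.0530, 0.134 and 0.134), and without both shallowest F344 libraries (0.824), which leaves 1 library in that group, assumed to vary like the others. Without these libraries the interferon call held with the preset correlation (adjusted p = 5.95e-10) but not with an estimated correlation (0.118). With an estimated correlation it also ended in 10 of 12 leave-outs, with the highest adjusted p, 0.242, without unstressed F344 replicate 1.

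Across all genes 19 differed without stress, 9 higher and 10 lower in WKY, and DESeq2 called 20. Park2, the ubiquitin ligase parkin, had 58 counts over the F344 libraries and 1 over the WKY libraries, a ratio of 94.2 (95% counting interval 16.3 to 3785), and edgeR gave an adjusted p of 1.26e-06. Whether WKY reads aligned to build rn6 as well as F344 reads was not tested, so few counts need not mean few transcripts. Plekhb1 stood at 25.7 ± 8.74 CPM in F344 and 1.97 ± 0.355 in WKY (log2 -3.68, SE 0.449, edgeR adjusted p = 1.26e-06); it overlaps Rab6a in the GRCr8 annotation. Also lower in WKY were the lipoxygenase Alox15 (log2 -1.69), the asparagine synthetase Asns (log2 -2.08), the protease Ctsb (log2 -1.33), the globin gene Hbb-b1 (log2 -1.5), the actin regulator Arpc2 (log2 -1.63) and Rpl35 (log2 -1.65). Higher were Ifi27 (log2 2.14), Lgals3bp (log2 2.09), Supt5h (log2 1.51) and Sav1 (log2 3.27), the last at 2.30, 31.1 and 15.5 CPM in the 3 WKY libraries. Globin and ribosomal protein genes have many copies, which leaves Hbb-b1 and Rpl35 uncertain. The count fell to 5 without unstressed F344 replicate 2, to 10 without replicate 3, and to 9 and 12 without unstressed WKY replicates 2 and 3, and rose to 45 without unstressed F344 replicate 1. It was 5 without both shallowest F344 libraries and 9 in a fit of these 6 libraries alone. Irf7, RT1-S3, Park2 and Plekhb1 passed whichever single library was left out. RT1-CE5 and the other called genes of this paragraph all missed the threshold without unstressed F344 replicate 2 (edgeR adjusted p from 0.0945 to 0.241). All of these but RT1-CE5 also missed it without unstressed WKY replicate 2 (0.0506 to 0.179). Without both shallowest F344 libraries RT1-S3 missed it too (adjusted p = 0.0638), and Alox15 (log2 -0.73, adjusted p = 0.855), Asns (log2 -1.15, 0.887), Ctsb (log2 -0.74, 0.804) and Hbb-b1 (log2 -0.88, 0.795) shrank by over 1.5 times.

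Leaving out other single libraries ended fewer of the calls without stress, and the log2 fold changes of the genes listed here moved by under 1.5 times. Without unstressed F344 replicate 3, the calls for Ifi27, Supt5h, Asns, Arpc2, Hbb-b1 and Ctsb ended (edgeR adjusted p from 0.0816 to 0.253). Without unstressed WKY replicate 1, those for Ifi27, RT1-CE5, Supt5h, Asns, Arpc2 and Ctsb ended (0.0592 to 0.208). Without unstressed WKY replicate 3, those for Ifi27, Rpl35, Arpc2, Hbb-b1 and Ctsb ended (0.0507 to 0.162). Without unstressed F344 replicate 1, those for Lgals3bp (0.0638) and Supt5h (0.101) ended, and without stressed F344 replicate 1 that for Supt5h (0.0508). Fkbp5 (log2 -0.30), Tsc22d3 (log2 -0.19), Nr3c1 (log2 0.19), Per1 (log2 -0.10) and Il1b (log2 0.12) did not pass.

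After CRS the interferon list was again higher in WKY, with 24 of 28 members positive, a median of 0.73, 7 past the threshold over all genes and 10 adjusted over the list alone (camera, adjusted p = 3.42e-10; adjusted p = 0.0230 with an estimated correlation). Irf7 stood at 308 ± 55.8 CPM in WKY and 88.5 ± 11.5 in F344 (log2 1.80, SE 0.286, edgeR adjusted p = 0.000197), and Mx2, an antiviral GTPase, at 8.99 ± 0.707 and 2.08 ± 0.869 (log2 2.04, SE 0.376, edgeR adjusted p = 0.00120). T cell genes were lower, 14 of 15 negative with a median of -0.52 (camera, adjusted p = 0.00408; adjusted p = 0.107 with an estimated correlation), as in Lef1 (log2 -1.08) and Cd3g (log2 -1.72), with 0 past 0.05 adjusted over the list alone. MHC class II genes were lower, 6 of 6 negative with a median of -0.96 and 2 past 0.05 adjusted over the list alone, RT1-Db1 (log2 -1.94) and RT1-Ba (log2 -1.24) (camera, adjusted p = 0.00385; adjusted p = 0.323 with an estimated correlation). Platelet genes were higher (median 0.60, adjusted p = 0.00710; adjusted p = 0.382 with an estimated correlation), among them Thbs1 (log2 1.20) and Cd9 (log2 1.13), with Gp1ba at log2 -1.01; 3 passed adjusted over the list alone. Oxidative phosphorylation genes were lower, 10 of 11 negative with a median of -0.38 (adjusted p = 0.0472; adjusted p = 0.349 with an estimated correlation), led by Ndufa1 (log2 -1.90) and Uqcrh (log2 -1.29), with 1 past the threshold over all genes and 2 adjusted over the list alone. The T cell and platelet calls were lost without stressed WKY replicate 2 (camera, adjusted p = 0.0565 and 0.104), which had the highest platelet and interferon sums (223 and 884 CPM), and the oxidative phosphorylation call held in 8 of 12 leave-outs. It was lost without stressed F344 replicate 2 or 3 or stressed WKY replicate 1 or 3 (adjusted p from 0.0790 to 0.250). Without both shallowest unstressed F344 libraries the interferon call held with the preset correlation (4.42e-10) but not with an estimated correlation (0.115). With an estimated correlation it also ended in 9 of 12 leave-outs, to 0.122 without stressed WKY replicate 3 and 0.0599 without replicate 2.

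Of single genes, 36 differed after CRS, 18 in each direction, and DESeq2 called 35. Park2 had 237 counts over the F344 libraries and 1 over the WKY libraries, a ratio of 171 (95% counting interval 30.5 to 6796), with an edgeR adjusted p of 4.78e-09. Plekhb1 had 253 and 7 counts (ratio 26.1, interval 12.5 to 65.7). Of the 7, 6 came from 1 stressed WKY library, so the size of the ratio depends on that library. The log2 fold change of Plekhb1 ran from -6.61 to -3.89 over the alternatives. Lower in WKY were Aamp (log2 -2.27), Rpl35 (log2 -1.96), Ndufa1, Alox15 (log2 -1.90), Rem2 (log2 -1.87), Hbb-b1 (log2 -1.85) and Arpc2 (log2 -1.44). Higher were Lgals3bp (log2 1.71), RT1-S3 (log2 1.61), Mpst (log2 1.58), RT1-CE5 (log2 1.48), Supt5h (log2 1.47), Slc40a1 (log2 1.40) and Slfn3 (log2 1.39). Mpst fell to log2 0.87 without stressed WKY replicate 2 (edgeR adjusted p = 0.388). Aamp, Mpst and Slc40a1 overlap other genes in the annotation. The count fell to 18, 19 and 20 without stressed F344 replicates 1, 2 and 3. Irf7, Mx2, RT1-S3, Park2, Plekhb1, Aamp, Rpl35, Alox15 and Hbb-b1 passed whichever single library was left out. Fkbp5 (log2 -0.88), Tsc22d3 (log2 0.56), Nr3c1 (log2 0.24), Per1 (log2 -0.23) and Il1b (log2 0.42) did not pass.

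Several calls after CRS ended when a single library was left out, while among the genes listed here the log2 fold change moved by over 1.5 times only for Mpst (to 0.87, without stressed WKY replicate 2). Without stressed F344 replicate 1, the calls for Lgals3bp, Mpst, RT1-CE5, Supt5h, Slc40a1, Slfn3, Ndufa1 and Arpc2 ended (edgeR adjusted p from 0.0569 to 0.263). Without stressed F344 replicate 2, those for RT1-CE5, Supt5h, Slc40a1, Ndufa1 and Rem2 ended (0.0855 to 0.289). Without stressed F344 replicate 3, those for Lgals3bp, Mpst, Supt5h, Slfn3, Ndufa1 and Arpc2 ended (0.0532 to 0.374). Leaving out stressed WKY replicate 1 ended those for Ndufa1, Rem2 and Arpc2 (0.106 to 0.203), replicate 2 those for Lgals3bp, Mpst, Supt5h and Slc40a1 (0.0663 to 0.388), and replicate 3 those for RT1-CE5, Slc40a1 and Arpc2 (0.0762 to 0.188).

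**Figure D3:**
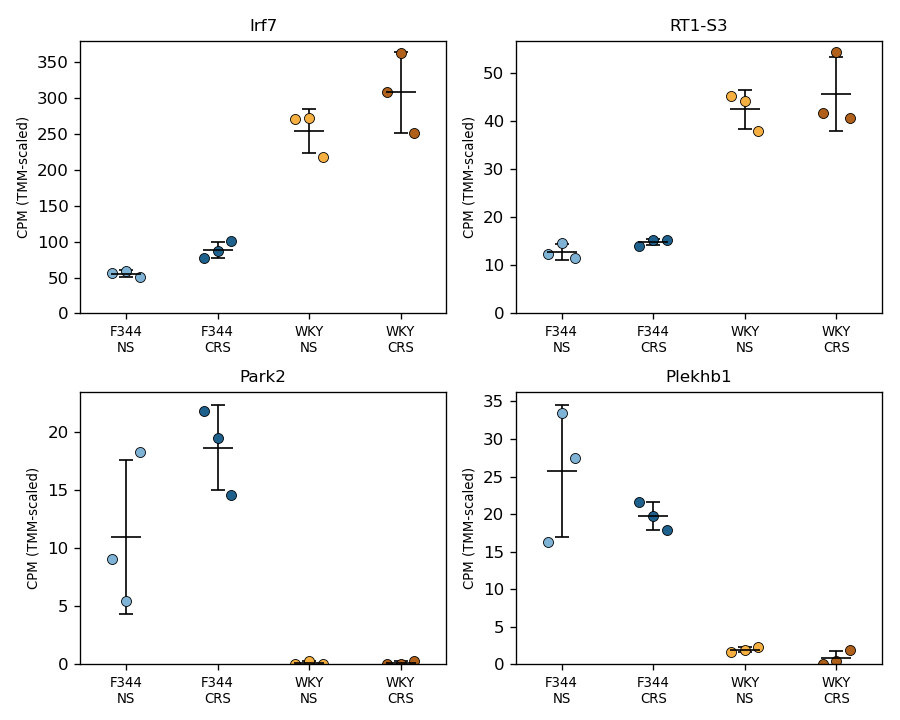
Levels of Irf7, RT1-S3, Park2 and Plekhb1 (CPM) in the 4 groups, with 1 point per library, horizontal bars for means and error bars for SD (n = 3). Irf7 averaged 254 and 308 CPM in the WKY groups and 55.3 and 88.5 CPM in the F344 groups, and each WKY library held 0 or 1 Park2 counts.

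Strain differences without stress and after CRS came from separate libraries and went the same way. Of 42 genes called in either, 39 had the same sign, and 13 were called in both, 6 higher and 7 lower in WKY, where independent lists would share 0.0583 and 0.0647. Across genes the fold changes correlated with Pearson's r = 0.384 and Spearman's rho = 0.293 (permutation p = 0.0099, the smallest that 100 draws give). The covariance was 0.153, and the highest in the draws was 0.0690. Pearson's r was 0.245 without unstressed F344 replicate 1 and 0.252 without both shallowest unstressed F344 libraries.

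Whether the strains responded differently to CRS was tested directly. MHC class II genes responded more negatively in WKY: 6 of 6 members were negative in this contrast, with a median log2 difference of -1.16 (camera, adjusted p = 0.00546; adjusted p = 0.445 with an estimated correlation), led by Cd74, the invariant chain (log2 -1.24), and the regulator Ciita (log2 -1.07), with 0 past 0.05 adjusted over the list alone. The summed list went from 51.3 ± 24.6 to 70.8 ± 5.16 CPM in F344 and from 72.4 ± 19.6 to 43.8 ± 10.8 CPM in WKY. Unstressed F344 replicates 1, 2 and 3 had sums of 78.6, 44.5 and 30.9 CPM, so replicate 1 lay above the stressed F344 libraries (64.9 to 74.1 CPM), and the higher mean after CRS rested on replicates 2 and 3. The call was lost without unstressed F344 replicate 3 (camera, adjusted p = 0.0722) and without unstressed WKY replicate 2 (adjusted p = 0.0514). For single genes edgeR called 0 of 2781, with 106 at an unadjusted p under 0.05, and DESeq2 called 0. The 3 smallest p-values in each direction, again among genes averaging at least 5 CPM with an informative symbol, belonged to Sav1 (log2 -4.20, SE 0.870, edgeR adjusted p = 0.0699), Foxe1 (log2 -3.23), Klf2 (log2 -1.57), Asns (log2 1.98), Sec14l1 (log2 1.5) and Stat5b (log2 1.30). Fkbp5 (log2 -0.58), Tsc22d3 (log2 0.76), Nr3c1 (log2 0.05), Per1 (log2 -0.14) and Il1b (log2 0.31) did not pass. Single libraries also moved this count, to 2, Sav1 and Foxe1, without unstressed WKY replicate 1 (edgeR adjusted p = 6.44e-05 and 8.84e-05) or stressed WKY replicate 1 (0.0498 for both), and to 1 without unstressed F344 replicate 2 or stressed WKY replicate 3.

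**Figure D4:**
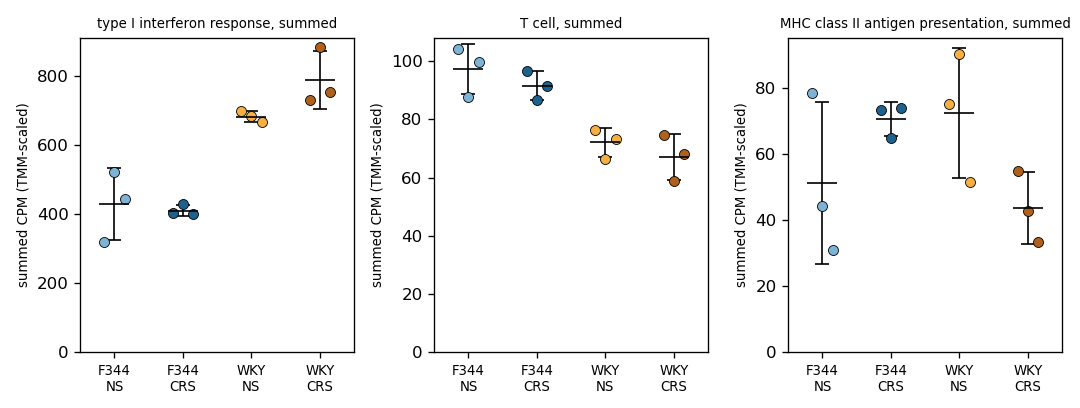
Summed CPM of the interferon, T cell and MHC class II lists in the 4 groups, with 1 point per library, horizontal bars for means and error bars for SD (n = 3). The interferon sums averaged 430 and 411 CPM in F344 and 684 and 790 CPM in WKY.

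The remaining lists were not called in any contrast by camera. Their smallest adjusted p-values were 0.0501 for antioxidant genes (CRS in WKY, median log2 0.34), 0.0522 for heat shock genes (CRS in F344, median log2 -0.62), 0.0785 for inflammatory cytokine genes (strain without stress, median log2 0.62) and 0.111 for globin (median log2 0.39) and B cell genes (median log2 -0.26), both for CRS in WKY. Proliferation genes reached 0.123, neutrophil genes 0.143, monocyte genes 0.154, erythroid genes 0.165 and immediate early genes 0.271. Medians, means and tests of called lists had the same sign. Among lists not called they differed in sign, for example for ribosomal protein genes between strains without stress (median log2 0.13, test downward). Lists with too few tested genes were compared as summed CPM only. Their CRS differences in F344 and WKY, on the log2 scale, were -0.60 and 0.24 for NK cell genes, which stood at 22.4 ± 2.79 and 14.6 ± 3.48 CPM in unstressed and stressed F344. They were 0.04 and -0.04 for plasma cell genes, 0.01 and -0.08 for stress hormone and monoamine genes, -0.31 and -0.04 for circadian genes, and 0.29 and -0.03 for eosinophil, basophil and mast cell genes. For tissue carried over at decapitation they were -0.78 and 0.10 for muscle and skin genes (7 to 48 counts per library), and -0.13 and 0.62 for neural genes (5 to 34 counts). Only the mean over both strains was tested, which does not show a change that goes opposite ways: the two-sided exact permutation p-values in this order were 0.39, 1, 0.69, 0.225, 0.62, 0.335 and 0.28. Adjusted over the 25 lists, none of the CRS differences in summed CPM passed 0.05; the smallest adjusted value was 0.125, for monocyte genes (log2 0.32, exact p = 0.005, the smallest possible).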

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

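The tests of B cell share, of a single library and of other groupings were chosen after the result was seen, and the criteria of the first 2 were revised after a first outcome. MHC class II genes differed between the strains in their response to CRS, with a median log2 difference of -1.157, and were singled out because both strains were compared under the same contrast and moved apart. Camera gave an adjusted p of 0.00546 with the preset correlation and 0.445 with an estimated correlation. The mean log2 level per library differed by -1.04 (SE 0.436) with an exact permutation p of 0.05, which is not under the threshold.

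A change in B cell share remained open. The MHC class II list responded below the B cell list by -0.61 (exact p = 0.05) as a mean level, by -0.89 (exact p = 0.025) as a sum and by -0.86 (permutation p = 0.00619) over genes. The weakest of these did not pass, so a difference in B cells may account for part of the pattern. The shallowest library, unstressed F344 replicate 3, also remained open: without it the difference was -0.77 (SE 0.383, exact p = 0.11), and camera gave an adjusted p of 0.0722. Why the call ended was not tested. Unstressed F344 replicate 2 stood apart from the other libraries as well; without both replicates 2 and 3 camera gave an adjusted p of 0.0387, with replicate 1 then the lone library of its group. Strain, which the design names, stays open beside these explanations. Groupings of the libraries were also drawn for single genes in this contrast. As the real count was 0, all 100 gave at least as many by construction (highest other 6), which says nothing about chance.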

How the results depend on the processing

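Leaving out both shallowest unstressed F344 libraries, removing the 3 most abundant features, and the averaged strain contrast were chosen after the data were seen; the other alternatives were planned. The first leaves 1 library in that group, assumed to vary like the others. Of 56 called results for named genes, 0 reversed under any alternative. All 56 kept their call with DESeq2 size factors, the stricter filter, the replicate block and removal of the 3 features; with globin removed 53 of 53 did. DESeq2 kept 53, limma-voom 50, no filter 48, fits of the compared groups 28 of 35, and removal of both shallow libraries 41. At this depth, with 3 libraries per group, contrasts not averaged over groups recovered 5.2% to 21% of simulated 2-fold changes; depth and the number of libraries were not varied separately. Settings without a library or with fewer genes test less; other causes were not tested.

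Called genes for CRS in F344 numbered 2 with limma-voom and 5 with no filter, and 0 to 5 when single libraries were left out. In WKY they numbered 8 with no filter, and 0 to 2. For CRS averaged over strains they numbered 3 with DESeq2, 2 with limma-voom, 6 with no filter (without Ppp4r2), 2 with the block, 2 at a threshold of 0.1, 0 without both shallow libraries, and 0 to 5. For strain without stress they numbered 9 in the fit of the compared groups, 41 at 0.1, 5 without both shallow libraries, and 5 to 45. After CRS they numbered 55 at 0.1, and 18 to 46. For the difference in response they numbered 3 with no filter, where the median of all genes was -0.24, 1 at 0.1, 1 without both shallow libraries, and 0 to 2. For strain averaged over treatments they numbered 43 without both shallow libraries, and 59 to 130.

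Called lists numbered 0 with an estimated correlation and 0 with fry for CRS in F344, in WKY and averaged, and for the difference in response. Between strains the preset correlation called 4 without stress, 5 after CRS and 5 averaged. An estimated correlation left 1, 1 and 2 in the same order, and fry called 4, 2 and 4. Without both shallow libraries there were 7 for CRS in F344, 9 averaged and 2 for the difference in response; with globin removed there were 2 for CRS in F344. Leaving out single libraries gave 1 to 3 for CRS in F344, 2 to 5 in WKY, 1 to 4 averaged, 3 to 6 for strain without stress, 3 to 5 after CRS, 4 to 7 averaged, and 0 to 2 for the difference.

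The correlation of strain differences between treatments was 0.518 with the stricter filter, 0.252 without both shallow libraries, and 0.245 (without unstressed F344 replicate 1) to 0.379 over leave-outs; that of CRS responses was 0.0639 to 0.136. The globin difference was 1.16 to 1.73 points. Replicate numbers were not taken to pair the libraries, since 4 of 18 same-numbered pairs had correlations over 0.1 (range -0.0901 to 0.204). Shared structure is not excluded: 9 of 12 libraries matched a same-numbered one best, although most candidates carried another number. The mean correlation of same-numbered pairs was 0.0402. That for other numbers, -0.0200, largely follows from it, since levels were centred within each group, and adds no evidence of its own. Alternatives for FPKM did not apply, since the files held counts.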

Other observations

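The averaged strain contrast, the summed list levels and the tests below were chosen after the result was seen, except the test of depth for platelet genes. The criteria of the tests against monocyte and T cell genes were also revised after a first outcome, so that all 3 measures had to pass. Averaged over treatments, WKY libraries had higher scaled counts of interferon-stimulated genes and lower ones of Park2, Plekhb1 and T cell genes than F344 libraries. The processing notes name only build rn6, and whether reads of both strains aligned to it equally well was not tested. Counts that recur after CRS do not settle this. Irf7 was higher (log2 2.00, SE 0.206, edgeR adjusted p = 1.25e-08), as were the antiviral genes Mx2 (log2 1.82), Oas3 (log2 1.42) and Mx1 (log2 1.28), with Lgals3bp (log2 1.90), Ifi27 (log2 1.85), RT1-S3 (log2 1.66), RT1-CE5 (log2 1.65) and Supt5h (log2 1.49). Lower were Park2 (log2 -6.57), Plekhb1 (log2 -4.15), Aamp (log2 -1.98), Rpl35 (log2 -1.80), Alox15 (log2 -1.79), Ndufa1 (log2 -1.76), Hbb-b1 (log2 -1.67), Arpc2 (log2 -1.54), the blood group gene Rhd (log2 -1.34) and Ctsb (log2 -1.29). In all 104 genes passed, 59 higher and 45 lower, and DESeq2 called 80. Oas3 and Rhd were not called without both shallowest unstressed F344 libraries (adjusted p = 0.0830 and 0.125), and Ndufa1 moved to log2 -2.86 without unstressed WKY replicate 1. Without unstressed F344 replicate 3, unstressed WKY replicate 2 or stressed F344 replicate 2 the count was 68, and without stressed F344 replicate 3 it was 59. Fkbp5 (log2 -0.59), Tsc22d3 (log2 0.18), Nr3c1 (log2 0.21), Per1 (log2 -0.17) and Il1b (log2 0.27) did not pass.

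Lists in this contrast were called as follows by camera. Interferon genes were higher, 25 of 28 positive with a median of 0.69, 10 past the threshold and 16 adjusted over the list alone (adjusted p = 1.10e-12; 0.0113 with an estimated correlation), including Oas1a (log2 3.64). T cell genes were lower, 13 of 15 negative with a median of -0.54, 1 past the threshold (Lef1, log2 -1.08) and 7 adjusted over the list alone (adjusted p = 0.000343; 0.0392 with an estimated correlation). Platelet genes were higher with a median of 0.68, 4 past the threshold, among them Thbs1 (edgeR adjusted p = 0.00359) and Itgb3 (log2 0.81), and 5 adjusted over the list alone (adjusted p = 0.000901; 0.479 with an estimated correlation), a call lost without both shallowest unstressed F344 libraries (0.160). MHC class I genes were higher with a median of 0.61 (adjusted p = 0.00279; 0.233 with an estimated correlation): 6 were higher and 2 lower past the threshold, the latter RT1-CE4 (log2 -1.25) and RT1-CE16 (log2 -1.03), and 8 and 2 adjusted over the list alone. Oxidative phosphorylation genes were lower with a median of -0.43 (adjusted p = 0.0378; 0.315 with an estimated correlation), a call held in 8 of 12 leave-outs and lost without unstressed F344 replicate 2, unstressed WKY replicate 3, stressed F344 replicate 3 or stressed WKY replicate 3 (adjusted p from 0.0537 to 0.131), or both shallowest unstressed F344 libraries (0.213). Without these libraries the interferon and T cell calls held with the preset correlation but not with an estimated correlation (adjusted p = 0.0517 and 0.0738). With an estimated correlation they also ended in 1 and 8 of 12 leave-outs, with the highest adjusted p, 0.0613 and 0.173, without unstressed F344 replicate 1.

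Explanations for the interferon difference were weighed. Depth was argued against as the whole cause, since without both shallowest unstressed F344 libraries the median was 0.72, no smaller than before, and camera gave an adjusted p of 6.234e-14 with the preset correlation (0.0517 with an estimated correlation). Unstressed F344 replicate 1 was then the lone library of its group, assumed to vary like the other groups. A rise of all leukocytes alike per red cell was argued against, since summed T cell genes were lower in WKY (log2 -0.44, exact p = 0.005). Interferon and T cell genes moved apart by 1.20, 1.29 and 1.55 on the log2 scale on the 3 measures, with p of at most 0.005 (the smallest the exact test gives). These lists were already called in opposite directions, so this test could hardly fail. More leukocytes of other types stay open: summed neutrophil genes differed by log2 0.33 (exact p = 0.015, 0.0625 adjusted over 25 lists) and erythroid genes by -0.09 (exact p = 0.65). More monocytes in WKY blood remained open and may account for part of the difference. Interferon genes lay above monocyte genes by 0.47 as a mean level (exact p = 0.005), but by 0.20 as a sum (exact p = 0.305) and 0.63 over genes (permutation p = 0.0927). Summed monocyte genes were higher in WKY (log2 0.60, exact p = 0.005, 0.025 adjusted over 25 lists), with Cybb (log2 1.73) and Lyz2 (log2 1.00) past the threshold. Lyz2 made up most of this: without stress it stood at 47.8 CPM in F344 and 98.4 in WKY, where the sums were 100 and 163 CPM. After CRS, Fn1 (log2 -0.72, edgeR adjusted p = 0.305) and Vcan (log2 -0.99, edgeR adjusted p = 0.569) had negative differences that did not pass over all genes. Adjusted over the list alone, Fn1 passed (0.0453) and Vcan did not (0.232). As a mean log2 level per library the list differed by 0.31 (exact p = 0.005), but camera did not call it. Strain, which the design names, also stays open, and what in the strains would differ was not tested.

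Explanations for the higher platelet genes after CRS, a call that did not hold with an estimated correlation (adjusted p = 0.493), were weighed as well. A fall in red cell transcripts was argued against as the whole cause, since platelet genes rose by 0.74 relative to T cell genes (exact p = 0.015). The platelet list was singled out for its rise, and summed T cell genes differed by log2 -0.09 (exact p = 0.195). This test thus largely restates the rise and could hardly fail. Summed B cell genes differed after CRS by log2 -0.15, erythroid genes by 0.03 and globin genes by 0.38, and none passed by exact permutation (p = 0.32, 0.87 and 0.09). Summed monocyte genes rose by 0.32 (exact p = 0.005, 0.125 adjusted over 25 lists), so a part of the platelet rise is not addressed. Deeper libraries after CRS could not be told apart from a rise. In 200 sets of libraries thinned to 90796 counts the median rise was 0.5438 (range 0.42 to 0.75, median exact p = 0.145), and on this scale the rise was 0.54 with exact p = 0.145 before thinning too. Thinning leaves the expected share of a list in each library unchanged, so the rise could not end by it. The test therefore says nothing for or against depth. Nor could the bound written beforehand, which asked for a p under the threshold, be met on this scale. In F344 the rise rested largely on the shallow unstressed replicates 2 and 3, and its call was lost without both (camera, adjusted p = 0.328). That fit leaves replicate 1, with a sum of 97.9 CPM against 110 to 127 CPM after CRS, as the lone library of its group, assumed to vary like the other groups. The lost call therefore says nothing for or against depth. In WKY the rise rested largely on unstressed replicate 3, at 77.4 CPM against 151 and 146 CPM in replicates 1 and 2: without it the rise of the sum fell from log2 0.60 to 0.29 and the call was lost (camera, adjusted p = 0.295). Averaged over strains the call held without both shallow F344 libraries (adjusted p = 0.00261) and without unstressed WKY replicate 3 (0.000329). With TMM scaling the summed rise was 0.65 (exact p = 0.02, 0.167 adjusted over 25 lists), so the result depends on the scaling. More platelets in the blood of stressed rats may account for the rise, and was not tested.

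Other groupings of the same libraries were tried for each count of genes. For the averaged strain contrast, 1 of 100 groupings, the real one with 104 genes, gave as many, and the highest other gave 10. Chance was thus unlikely to give this count, within the limit of 100 groupings. This contrast and its test were chosen after the data were seen. For CRS averaged over strains, 25 of 100 gave at least the 1 gene of the real one, and the highest other gave 5, so chance could not be excluded. The comparisons of 3 libraries with 3 allow 10 groupings, too few for a share under 0.05. For strain without stress 1 of 10 gave the real 19 (highest other 2), and after CRS 1 of 10 gave the real 36 (highest other 1). For CRS in F344 and in WKY the real count was 0, so 10 of 10 gave at least as many by construction (highest other 1 and 6), which says nothing about chance.

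Tested neighbours of Plekhb1 did not share its lower level in WKY: Rab6a (log2 0.01, adjusted p = 0.991) and Ucp2 (log2 -0.17, adjusted p = 0.810) did not pass. Over both treatments Park2 had 295 and 2 counts, a ratio of 150 (95% counting interval 41.1 to 1242), and Plekhb1 391 and 26 (ratio 15.3, interval 10.3 to 23.7). Summed eosinophil, basophil and mast cell genes were lower in WKY (log2 -1.61, exact p = 0.005), but without Alox15 the other 11 genes were higher, at 5.07 ± 3.00 CPM in WKY and 2.31 ± 1.10 in F344 (log2 0.82, exact p = 0.03, 1 to 25 counts per library). The lower sum was therefore that of Alox15. Summed neutrophil genes differed by log2 0.33 (exact p = 0.015, 0.0625 adjusted over 25 lists), and summed platelet genes by log2 0.67 (exact p = 0.025, adjusted 0.0893).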
